A study of Homo sapiens with 85 samples.

How the data were processed

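Messenger RNA of human tissue was measured on 85 Affymetrix U133A 2.0 arrays: 66 of desmoid tumor, 8 of normal muscle and 11 of normal fat. Per the labels' protocols, tissue was macrodissected after a pathologist had looked at it, RNA was purified on RNeasy columns, cDNA was made with an oligo-dT primer carrying a T7 promoter, and biotin-labelled cRNA was hybridised. The authors' deposited table holds log2 expression values, 1 per probe set and array, summarised with GCRMA per the submitters' processing notes, which give no version. Whether all arrays were normalised together is not stated. The log2 scale was read from the values themselves, which ran from 2.16 to 16.20.

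The table held 22215 probe sets. Gene names came from a reference table that pairs the platform's probe sets with genes: 19064 probe sets named 1 gene, 1043 named several and 2108 named none, and the last 2 kinds were left out of gene counts. The Entrez identifiers of 12 probe sets had no match among RefSeq genes and kept the symbol of that table. Because the samples are human tissues, 31 probe sets of Y-linked genes and XIST were removed. For each gene the probe set with the highest mean of the 3 group means was used, which left 11939 genes, 4304 of them with several probe sets. No filter on dim genes was applied. A value within 0.1 of a probe set's lowest value, where that lay under 4, was counted as at its lowest value. Depth is not counted on arrays, and the number of arrays limits the precision.

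Desmoid tumor was compared with normal muscle and with normal fat, and normal muscle with normal fat, in 1 limma model of the 3 groups (limma 3.58.1 in R 4.3.3; lmFit, then eBayes with trend=TRUE; 82 residual and 0.82 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05 and a difference of at least 2-fold. Genes called with the same sign in both tumor comparisons were counted and set beside the number that independent lists would share. Differences are given in log2 with their standard error (SE), group means with their standard deviation (SD). P-values measure the spread between these arrays, since the labels give no donors, batches or scan dates.

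The 22 gene lists were written from general knowledge. They cover HIF1 targets and angiogenesis, the PDGF family, ABL kinases and substrates, targets of Wnt and beta-catenin, TGF-beta and Notch signalling, kinase inhibitor targets, proliferation, oxidative phosphorylation, the immediate-early response, and markers of fibroblasts and matrix, skeletal muscle, adipocytes, endothelium, pericytes and smooth muscle, macrophages, lymphocytes, mast cells, erythrocytes, nerve and epithelium. Each was tested with limma's camera (preset correlation between genes of 0.01), adjusted over the 44 list tests. A p from camera with the correlation estimated from the arrays is given beside it. Limma's fry was run as well. It tests whether a list's genes move one way on balance, with no comparison to other genes.

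All arrays were clustered on the 128 measured genes of the HIF1 and angiogenesis lists. Each gene was scaled to mean 0 and SD 1, the distance was 1 minus Pearson's r, and average linkage was divided into 3 clusters. The adjusted Rand index (1 for a perfect match with the 3 tissues, near 0 for none) and the silhouette width were set beside 1000 random lists matched on mean expression in 20 bins, and tissue labels were permuted 100000 times. Correlations over the 66 desmoid arrays were tested for 11 pairs of genes by two-sided permutation (100000), adjusted over the 11 pairs, and r was computed again without the 2 arrays farthest from the median of the first gene. These steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

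The groups, comparisons, tests, thresholds, lists, gene pairs and most alternatives were fixed before the data were examined. So was the rule for naming genes: 15 genes the study is about, the 5 highest and 5 lowest called genes of each tumor comparison, up to 3 called genes of each list described, the 8 highest and 8 lowest genes called against both tissues, and the 3 highest and 3 lowest between muscle and fat, with at most 30 per comparison. Which list genes filled those 30 places was settled after their values were seen, by taking the largest differences first.

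Each method was tested on simulated data first. Among the 11939 genes, with 100 genes changed by 1.5 (log2), 94% were called with the right sign in a simulated comparison of desmoid tumor with normal muscle and 96% in one with normal fat, and 100% in both at a change of 3, with 2 and 1 false calls. The changed genes were drawn from those of intermediate mean expression, and each gene had the same SD in every group. The shares called therefore do not cover dim genes. The false calls do not cover genes whose SD differs between tissues. A shifted angiogenesis list was called in both simulated tumor comparisons, and none of 16 lists sharing no gene with it was. The simulated genes were drawn independently of each other, so this could not show false calls of lists whose genes move together. On the real arrays the correlation estimated within a list reached 0.872, for skeletal muscle markers. Clustering gave a Rand index of 0.872 with planted tissues and -0.008 without. The planted correlation was called, with 0 calls among the others. In 20 simulated sets of unchanged groups, again with the same SD in every group, 0 genes were called.

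The alternatives tried were filters at a highest group mean of 4 and 6, the mean of a gene's probe sets, the probe set with the highest SD, quantile normalization, centring each array on its median, a robust fit without the trend, array quality weights, averaging arrays that share a specimen number, leaving out each normal array, fitting only the groups compared, other linkages and gene choices for the clustering, and partial correlations. Chosen after seeing the data were leaving out normal fat 9 and desmoid 44, leaving out 15 desmoid arrays rich in muscle or fat transcripts, leaving out desmoid 6, and both scalings for the gene lists. In 2 pairs of arrays the labels share a specimen number. The arrays of these pairs had an r of 0.979 and 0.983 over probe sets. In each pair 1 array was closer to another array of its group (0.983 and 0.990). The other array, normal fat 9 or desmoid 44, was closest to its partner, with at most 0.967 and 0.979 to the rest of its group. By the rule fixed earlier, which asked this of both arrays, all 85 arrays were kept apart. That does not show that they come from different specimens, so averaging both pairs was among the alternatives. Measures of RNA quality from control probe sets were left out because the table holds 0 of these, and the pair of CTNNB1 with AXIN2 because AXIN2 was not among the genes measured.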

Results

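Expression of 11939 genes was measured on 66 arrays of desmoid tumor, 8 of normal muscle and 11 of normal fat. In 1 pair of desmoid and 1 pair of fat arrays the labels share a specimen number, so there may be fewer specimens than arrays, and counts of tumors below are counts of arrays. Desmoid tumors are locally invasive growths of fibroblast-like cells in which beta-catenin, the product of CTNNB1, is often stabilized. The study is about PDGFRB, beta-catenin and the kinase ABL, and its design placed the tumors beside normal tissue for targets of HIF1, the factor that switches genes on when oxygen is low, and for genes of blood vessel growth. Values are log2 array intensities of messenger RNA, so they do not show protein levels or kinase activity. All differences are in log2 as tumor minus normal tissue. The share of values at the lowest level of the table was 30.6% ± 0.690 (SD) in desmoid tumors, and somewhat lower in muscle, at 28.8% ± 0.238, and in fat, at 29.6% ± 1.51. Where arrays of a group lie at a gene's lowest value, the background limits both the size of a difference and its rank. The 8 and 11 normal arrays limited the precision. The labels give no donor or batch, so p-values measure the spread between these arrays. For each gene that spread is shared by the 3 groups and comes mostly from the 66 tumor arrays. Where a normal tissue varies more than the tumors, the SE and the p may be too small. THBS2, for example, had an SD of 1.34 in muscle and 0.29 in tumors.

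Desmoid tumors differed from normal muscle in 39.6% of the genes tested. They held far higher levels of a set of fibroblast and matrix genes, which averaged 12.50 in the tumors and 6.64 in muscle, and far lower levels of muscle's contractile and energy-making transcripts. Transcripts of CTNNB1, both PDGF receptors, 3 of the 4 PDGF ligands, ABL1 and HIF1A were all higher in the tumors. VEGFA, the main growth factor for blood vessels, was lower. In all, 2718 genes were called higher and 2004 lower, 4722 together, by limma at an adjusted p under 0.05 and at least 2-fold.

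Of the 15 genes the study is about, 10 were called, and PDGFB, ABL2, APC, EPAS1 and FLT1 were not. CTNNB1 averaged 13.10 ± 0.26 (SD, n = 66) in desmoid tumors and 11.22 ± 0.32 (n = 8) in muscle, a difference of 1.88 (SE 0.10, limma adjusted p 1.93e-30), and all 66 tumors lay above every muscle array. PDGFRB, the receptor in the study's title, averaged 9.78 ± 0.32 against 7.11 ± 0.40, a difference of 2.66 (SE 0.12, adjusted p 3.36e-34), again in 66 of 66 tumors. PDGFRA, the sister receptor, was higher by 2.22 (adjusted p 9.29e-19), though by 0.97 and so not called when its probe sets were averaged. Among the ligands, PDGFD was higher by 3.06, PDGFC by 2.17 and PDGFA by 1.53, while PDGFB sat at 3.71 and 3.72 in the 2 tissues and was not called. ABL1 rose by 1.33 (adjusted p 1.25e-16), and by 0.85, under the threshold, once each array was centred on its median. ABL2 was low, averaging 2.76 in the tumors and at its lowest value in all 8 muscle arrays, and was not called. APC, the brake on beta-catenin, was higher by 0.46, under 2-fold.

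HIF1A, the oxygen-regulated subunit of HIF1, showed the largest change of the 15 study genes, 24.5-fold higher in the tumors (4.61, SE 0.17, adjusted p 1.52e-41), with 66 of 66 tumors above every muscle array. EPAS1, which encodes the related HIF2-alpha, differed by 0.65, under 2-fold. VEGFA averaged 9.50 ± 0.64 in desmoid tumors and 11.58 ± 0.57 in muscle, a difference of -2.08 (SE 0.24, adjusted p 1.19e-12), and 65 of 66 tumors lay below every muscle array. Its receptor KDR was higher by 2.24 and its receptor FLT1 lower by less than the threshold, at -0.81, although FLT1 was called at -1.11 after quantile normalization and at -1.29 after median centring.

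**Figure D1:**
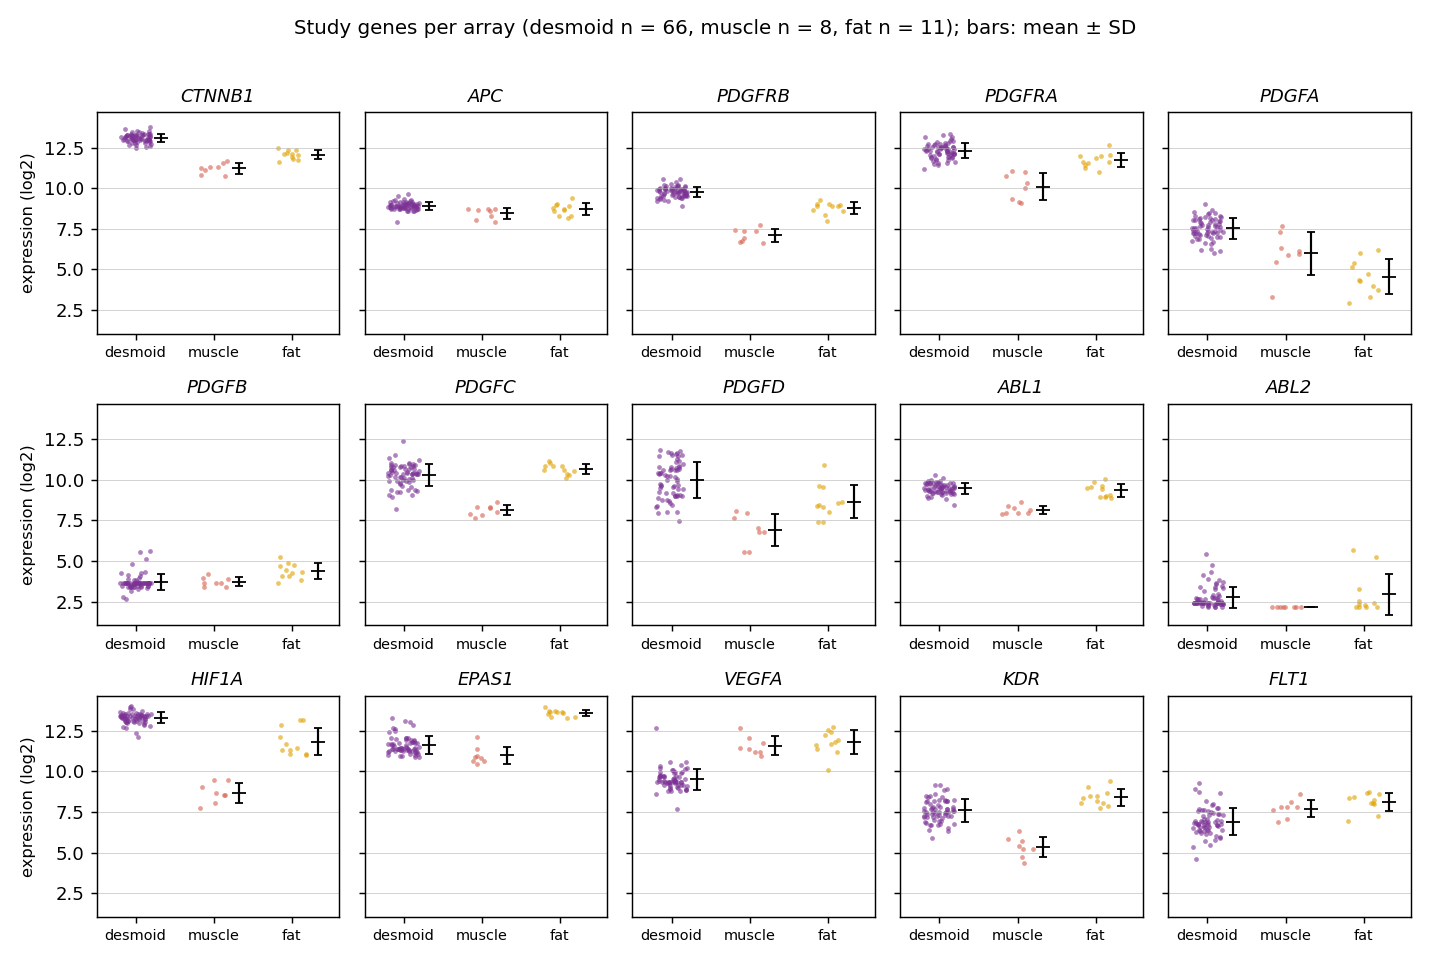
Log2 expression of the 15 study genes in each array, by tissue (66 desmoid tumor, 8 normal muscle and 11 normal fat arrays), with group means and SD as bars. HIF1A averages 13.29 in desmoid tumors, 8.68 in muscle and 11.83 in fat, and VEGFA 9.50, 11.58 and 11.79.

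The fibroblast and matrix genes had the highest median of the 22 lists. Of 43 measured members, 42 were higher and 0 lower, with a median difference of 6.03. COL11A1, a collagen chain, went from 2.76 to 13.49, a difference of 10.72 (SE 0.43, adjusted p 9.42e-39). LRRC15, a membrane protein of activated fibroblasts, was higher by 10.43, MFAP2, a part of elastic microfibrils, by 10.03 and the matrix protein SPON1 by 9.92. THBS2, a matrix protein that restrains vessel growth, was higher by 8.89, and LOX, which cross-links collagen and is also a HIF1 target, by 8.94. TMEM45A, another HIF1 target on the list, was higher by 9.62. LRRC15 and MFAP2 were at their lowest values in 3 of the 8 muscle arrays. Each of these 7 genes was above every muscle array in 66 of 66 tumors.

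Muscle's own transcripts were far lower. All 33 skeletal muscle markers were lower, with a median of -10.77. The contractile proteins TNNC1 and TNNT1 differed by -11.70 and -11.68, the energy enzymes CKM and PYGM by -11.90 and -11.80, and EEF1A2, the muscle form of a translation factor, by -11.94 (SE 0.25, adjusted p 7.65e-60). TNNC1, TNNT1, CKM, PYGM and EEF1A2 were at their lowest values in 49, 51, 51, 57 and 52 of the 66 tumors, so the background limits the sizes and the order of these differences. The difference was uneven between tumors: CKM averaged 3.78 ± 3.43 in desmoid tumors, and in 12 tumors the mean of the muscle markers was over 5. Oxidative phosphorylation went the same way, with 40 of 44 genes lower, 0 higher and a median of -1.69, and COX6A2, a muscle form of a respiratory chain subunit, differed by -10.09, with 54 tumors at its lowest value.

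Most genes of the angiogenesis list were higher and HIF1 targets split. The angiogenesis list mixes genes that promote and that restrain vessel growth, so its counts give no direction of vessel growth. THBS2, which restrains it, differed by 8.89 and VEGFA by -2.08. In the angiogenesis list, 42 of 71 measured genes were higher and 5 lower, with 24 not called and a median of 1.91. Without the genes also on a cell type list, 37 of 66 were higher and 5 lower. Those removed were all fibroblast and matrix genes. The VEGFA receptors KDR and FLT1 stayed in, so this count does not set vessel cells aside. Of 60 measured HIF1 targets, 23 were higher, 17 lower and 20 not called. The HIF1 median of 0.26 became 0.01 after quantile normalization and -0.22 after median centring. Endothelial markers gave 4 higher and 3 lower of 19, and pericyte and smooth muscle markers 6 higher and 5 lower of 15. Their medians of 0.05 and 0.20 also turned negative under both scalings, and the pericyte mean was -0.78. DES and CASQ2 pulled that mean down, at -9.10 and -7.89, and averaged 14.53 and 12.19 in muscle. The mean can therefore not be read as a loss of pericytes.

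The signalling lists leaned upward. Targets of Wnt and beta-catenin had 16 higher and 4 lower of 28, among them the transcription factor TWIST1 at 8.68 (SE 0.20, adjusted p 1.76e-56) and CCN4, a secreted growth regulator. CCN4 was at its lowest value in all 8 muscle arrays, so its difference was at least 6.96. The PDGF family had 5 higher and 0 lower of 6, the TGF-beta pathway 13 and 2 of 21, kinase inhibitor targets 8 and 1 of 16, ABL kinases and substrates 7 and 2 of 15, and the Notch pathway 6 and 2 of 17. Notch was even under other scalings, with 6 higher and 5 lower after quantile normalization and 5 and 5 after median centring, where its median of 0.35 became -0.13. Proliferation genes had 15 higher and 1 lower of 32, with TYMS, which makes thymidylate for DNA synthesis, higher by 5.92 (SE 0.32, adjusted p 1.59e-30) and at its lowest value in 4 of the 8 muscle arrays.

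Among markers of other cell types, those of adipocytes had 12 lower and 1 higher of 20, with a median of -2.25. Of these, GPD1 and G0S2 differed by -7.78 and -7.74 and averaged 10.39 and 11.78 in muscle. The adipocyte count therefore does not separate fat cells from muscle's own expression. Macrophage markers had 9 higher and 0 lower of 21, and mast cell markers 3 higher and 0 lower of 6. The macrophage counts became 6 and 1 after quantile normalization and 5 and 1 after median centring, where the median of 0.58 became 0.23 and 0.10. Immediate-early genes, which respond within minutes to stress, had 11 lower and 3 higher of 18. The difference was uneven: their mean ranged from 7.45 to 12.16 over muscle arrays (SD 1.82) and from 7.31 to 11.39 over tumors. Lymphocyte and plasma cell markers had 1 higher and 1 lower of 20, erythrocyte markers 0 and 1 of 5, nerve markers 1 and 1 of 7, and epithelial markers 2 and 0 of 14. Medians of the lymphocyte, nerve and epithelial lists, all within 0.12 of 0, turned negative after median centring.

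Tested against all other genes with limma's camera at its preset correlation, 6 of the 22 lists passed the threshold against muscle and 7 against fat, 13 in all. Random splits of the arrays gave a median of 13 such calls, and 59 of 100 splits gave as many as the real one. The number of calls therefore does not exclude chance, but the splits do not judge any single list. The fibroblast and matrix mean was 10.97 or more in every tumor and 7.41 or less in every muscle array. The skeletal muscle mean reached 11.26 in tumors and was 13.80 or more in muscle. Adipocyte means overlapped, from 3.32 to 10.03 in tumors and 5.96 to 8.33 in muscle. Against muscle the adjusted p was 6.56e-23 for fibroblast and matrix, 4.03e-21 for oxidative phosphorylation, 2.70e-12 for skeletal muscle, 1.28e-05 for angiogenesis, 0.0217 for Wnt targets and 0.0299 for adipocyte markers. With the correlation between genes estimated from the arrays, the p for fibroblast and matrix was 0.0226 and those of the others were 0.113, 0.481, 0.0703, 0.0997 and 0.904. HIF1 targets had an adjusted p of 0.758. The nearest of the uncalled lists were proliferation, TGF-beta and kinase inhibitor targets at 0.0516 each and the PDGF family at 0.0554. ABL substrates gave 0.223, immediate-early genes 0.319, Notch 0.543, mast cells 0.614, macrophages 0.635, erythrocytes 0.688 and pericytes 0.917, and endothelial, lymphocyte, nerve and epithelial markers 0.758 each. Adjusted over the list alone, member counts equalled those over all genes except for lymphocyte markers, with 0 higher and 1 lower. Centring each array on its median moved the median of all genes by -0.48 and the share of called genes that were higher from 57.6% to 42.4%, so the balance of directions depends on the scaling.

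Against normal fat, desmoid tumors were again higher in matrix genes and far lower in those of fat cells. Transcripts of CTNNB1, PDGFRB, PDGFA, PDGFD and HIF1A were again higher, by less than against muscle for all but PDGFA. ABL1 and PDGFC were not called. VEGFA and EPAS1 were lower. Of the cell type and response lists, 18 of 21 macrophage, 15 of 18 immediate-early and 10 of 19 endothelial genes were lower and 17 of 32 proliferation genes higher, but none of these 4 lists passed with an estimated correlation between genes. In all, 1566 genes were called higher and 1351 lower, 2917 together.

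Of the study genes, CTNNB1 averaged 12.06 ± 0.27 (n = 11) in fat, 1.04 below the tumors (SE 0.09, limma adjusted p 1.61e-18), and 65 of 66 tumors lay above every fat array. That difference fell to 0.91 after median centring and 0.99 without normal fat 7, both under the 2-fold threshold. PDGFRB averaged 8.78 ± 0.37 in fat, 2-fold below the tumors (SE 0.11 in log2, adjusted p 1.57e-13), and 63 of 66 tumors lay above every fat array. PDGFRB stood at the threshold itself and was not called in 9 alternatives (0.88 to 0.99), among them averaging the arrays that share a specimen number (0.96), quantile normalization (0.94) and leaving out normal fat 5 (0.98), 6 (0.96), 9 (0.92) or 11 (0.99). PDGFA was higher by 2.98 (SE 0.25, adjusted p 3.32e-18) and PDGFD by 1.34 (SE 0.35, adjusted p 7.31e-04). PDGFRA at 0.58, PDGFC at -0.36 and PDGFB at -0.67 were under 2-fold. ABL1 differed by 0.13 (adjusted p 0.36), ABL2 by -0.18 and APC by 0.22.

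HIF1A was higher by 1.46 (SE 0.15, adjusted p 7.66e-15), with 47 of 66 tumors above every fat array. EPAS1, abundant in fat at 13.60 ± 0.20, differed by -1.97 (SE 0.17, adjusted p 3.15e-18), and all 66 tumors lay below every fat array. VEGFA differed by -2.28 (SE 0.21, adjusted p 1.04e-16), with 58 of 66 tumors below every fat array. KDR was lower by less than the threshold, at -0.80, and FLT1 was called at -1.22, but not at -0.75 when its probe sets were averaged.

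Of 43 fibroblast and matrix genes, 40 were higher and 0 lower, with a median of 3.66. COL11A1 was higher by 11.04 (SE 0.38, adjusted p 7.78e-43) and LRRC15 by 9.76 (SE 0.19, adjusted p 6.01e-60). MMP11, a secreted protease of tumor stroma, was higher by 8.53, LAMP5, a membrane protein, by 8.35 and FBN2, a microfibril protein, by 7.76. MMP11, LAMP5 and FBN2 were at their lowest values in 8, 10 and 5 of the 11 fat arrays, so the sizes of these differences are limited by the background. Proliferation genes had 17 higher and 0 lower of 32, and TYMS was higher by 4.69. Wnt targets had 10 higher and 8 lower of 28. Among them, CCN4 was at its lowest value in all 11 fat arrays and so higher by at least 6.96.

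Fat cell transcripts were far lower: 19 of 20 adipocyte markers were lower and 0 higher, with a median of -7.51. PLIN1, which coats lipid droplets, differed by -10.47 (SE 0.67, adjusted p 4.65e-25), and the hormones ADIPOQ and LEP by -10.25 and -10.08. ADH1B, an alcohol dehydrogenase, differed by -10.14 and PPP1R1A, an inhibitor of a protein phosphatase, by -9.91. PLIN1, ADIPOQ, LEP, ADH1B and PPP1R1A were at their lowest values in 50, 45, 52, 38 and 49 of the 66 tumors, so the background limits the sizes and the order of these differences. Macrophage markers had 18 of 21 lower and 0 higher, with MARCO, a scavenger receptor, at -3.98 and at its lowest value in 61 tumors. Endothelial markers had 10 of 19 lower and 1 higher, with a median of -1.28. Immediate-early genes had 15 of 18 lower and 0 higher, and FOSB differed by -5.52 (SE 0.72, adjusted p 1.31e-10).

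HIF1 and angiogenesis genes went both ways against fat. Of 60 HIF1 targets, 12 were higher, 14 lower and 34 not called. TF, the iron carrier transferrin, differed by -7.67 (SE 0.30, adjusted p 1.77e-38), with 56 tumors at its lowest value, while LOX and TMEM45A were higher by 3.42 and 5.21. Of 71 angiogenesis genes, 20 were higher and 20 lower, with a median of -0.08. Without the same fibroblast and matrix genes, 15 of 66 were higher and 20 lower. The PDGF family had 3 higher and 0 lower of 6, with 2 higher under either scaling.

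The remaining lists showed few calls in either direction or an even balance. TGF-beta had 8 higher and 5 lower of 21, and pericyte markers 4 and 4 of 15, with a median of 0.07 that became -0.05 under either scaling. ABL substrates had 2 and 2 of 15, kinase inhibitor targets 2 and 2 of 16, Notch 2 and 1 of 17, nerve markers 2 and 2 of 7, epithelial markers 2 and 1 of 14, mast cell markers 1 and 0 of 6, erythrocyte markers 0 and 1 of 5, and lymphocyte markers 0 and 0 of 20. Oxidative phosphorylation had 1 and 1 of 44, and skeletal muscle markers 1 and 0 of 33, or 0 and 0 adjusted over the list alone.

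With limma's camera at its preset correlation, 7 lists passed the threshold against fat, with the same limit that random splits gave as many calls in all. The adjusted p was 2.75e-26 for fibroblast and matrix, 5.09e-19 for adipocyte markers, 2.72e-06 for macrophage markers, 4.07e-05 for immediate-early genes, 1.94e-04 for proliferation, 9.18e-04 for endothelial markers and 0.00754 for oxidative phosphorylation. With an estimated correlation the p for fibroblast and matrix was 0.0188 and those of the others were 0.0601, 0.481, 0.481, 0.657, 0.617 and 0.904. HIF1 targets had an adjusted p of 0.869, where the median of 0.01 and the mean of -0.13 differed in sign, and angiogenesis 0.751. The adjusted p was 0.168 for erythrocyte markers, 0.211 for TGF-beta, 0.439 for the PDGF family, 0.543 for nerve markers, 0.723 for Wnt targets, 0.731 for pericytes, 0.751 for skeletal muscle, 0.758 for kinase inhibitor targets, 0.88 for mast cells and 0.997 for ABL substrates, and it was 0.917 for lymphocyte, epithelial and Notch genes. Median centring moved the median of all genes by -0.12 and the share higher from 53.7% to 47.6%.

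**Figure D2:**
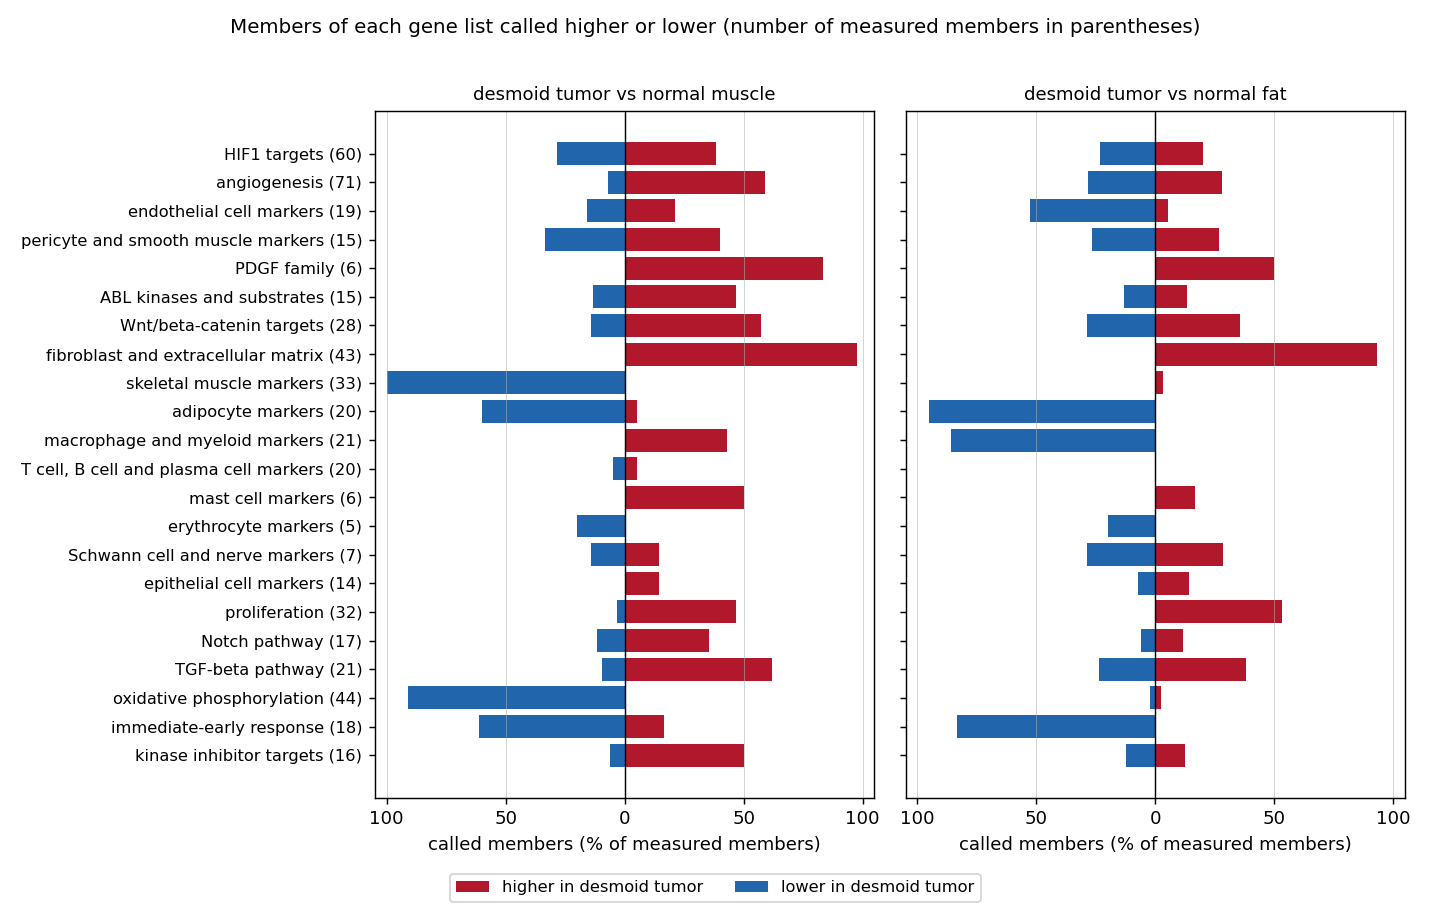
Share of the measured members of each of the 22 gene lists that was called higher (right of 0) or lower (left of 0) in desmoid tumors, in % of members, against normal muscle and normal fat. Fibroblast and matrix genes were higher in 42 and 40 of 43 members, at the deposited scaling, and HIF1 targets divide in both comparisons.

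Genes called the same way against both tissues differed in 1 direction between the tumors and either normal tissue. They do not separate a change within cells from a different mix of cells. The fibroblast and matrix list, for example, averaged 12.50 in tumors, 6.64 in muscle and 8.56 in fat. There were 1704 of them, 1172 higher and 532 lower, where independent lists would share 356.5 and 226.8. The 8 leading higher genes, several of them for matrix, averaged under 4 in both normal tissues. The 8 leading lower genes were expressed in both, and GPD1, G0S2 and PDK4 among them act in fuel use.

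Ranked by the smaller of the 2 differences, the 8 leading higher genes were COL11A1, LRRC15, MMP11, LAMP5, FBN2, GREM1, SDC1 and PTK7. GREM1, which blocks bone morphogenetic proteins, was higher by 7.69 against muscle and 7.71 against fat. SDC1, a cell surface proteoglycan, was higher by 7.43 and 7.74, and PTK7, a receptor-like protein in Wnt signalling, by 7.34 and 7.74. MMP11 was at its lowest value in all 8 muscle arrays, so its difference from muscle was at least 8.65, and LAMP5 and FBN2 were at theirs in 7 of the 8. SDC1 was at its lowest value in 8 of the 11 fat arrays. Of these 8 genes, COL11A1, LRRC15, MMP11, FBN2, SDC1 and PTK7 were above every muscle and every fat array in 66 of 66 tumors, and LAMP5 was above every array of each tissue in 65.

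The 8 leading lower genes were PPP1R1A, GPD1, G0S2, ZBTB16, APOD, MAOB, GPX3 and PDK4. GPD1, which links sugar and fat metabolism, differed by -7.78 from muscle and -9.50 from fat, G0S2, an inhibitor of fat breakdown, by -7.74 and -8.98, and PDK4, which turns off pyruvate oxidation, by -9.41 and -6.43. ZBTB16, a transcription factor, differed by -8.34 and -6.71 and MAOB, an amine oxidase, by -6.64 and -7.05. The lipid carrier APOD differed by -7.23 and -6.68 and the secreted peroxidase GPX3 by -6.44 and -7.64. GPD1, PDK4, ZBTB16, PPP1R1A and MAOB were at their lowest values in 57, 56, 51, 49 and 26 of the 66 tumors, which limits the sizes and the ranking. All 66 tumors lay below every muscle and every fat array for PPP1R1A and MAOB.

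Another 262 genes were called in opposite directions against the 2 tissues. Because both comparisons share the tumor arrays, the overlap was counted again with the tumors divided between them. The medians over 20 divisions were 1165.5 higher and 532.5 lower. With many tumors on each side of a division, so close a match could be foreseen. The same tissue still stands in both comparisons, so the counts from independent lists are no measure of what chance would give. Median centring lowered the share that was higher from 68.8% to 55.9%.

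The normal tissues also differed widely from each other. Muscle against fat gave 4355 genes, 1842 higher and 2513 lower in muscle. In log2 as muscle minus fat, the contractile and energy genes TNNC1, CKM and TNNT1 led at 13.08, 12.93 and 12.78 (TNNT1 SE 1.26, limma adjusted p 2.06e-15). The tumors widen that SE through the shared spread: TNNT1 had an SD of 3.03 in tumors, 0.19 in muscle and 0.98 in fat. LEP at -9.84, CIDEA, a lipid droplet protein, at -8.70 and EPB41L4B, a cytoskeletal linker, at -7.81 were furthest the other way. TNNC1, CKM and TNNT1 were at their lowest values in 10 of the 11 fat arrays each, and LEP, CIDEA and EPB41L4B at theirs in 4, 5 and 5 of the 8 muscle arrays. Median centring moved the median of all genes by 0.36 and raised the share higher in muscle from 42.3% to 55.4%.

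Clustering on the HIF1 and angiogenesis genes separated nearly all tumors from normal tissue. Of 3 clusters, 1 held all 8 muscle and 11 fat arrays with 2 desmoid tumors, both of which were over the limit for muscle or fat markers, and the others held 57 and 7 desmoid tumors. Muscle and fat came apart at 5 clusters, with the 2 tumors beside the fat. The mean of the HIF1 targets was 8.55 ± 0.24 in desmoid tumors, 7.92 ± 0.30 in muscle and 8.68 ± 0.20 in fat, and that of the angiogenesis genes 8.52 ± 0.18, 6.62 ± 0.34 and 8.69 ± 0.24, means over members that went both ways against fat. Random lists of genes separated the tissues as well: the adjusted Rand index was 0.632, and 703 of 1000 matched random lists reached it, with a median of 0.778. The silhouette width was 0.42, which 207 of the 1000 reached. Against permuted tissue labels the index had a p of 1e-05, the smallest that 100000 permutations can give. With Ward linkage the clusters held 8 muscle arrays, 62 tumors, and 11 fat arrays with 4 tumors.

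**Figure D3:**
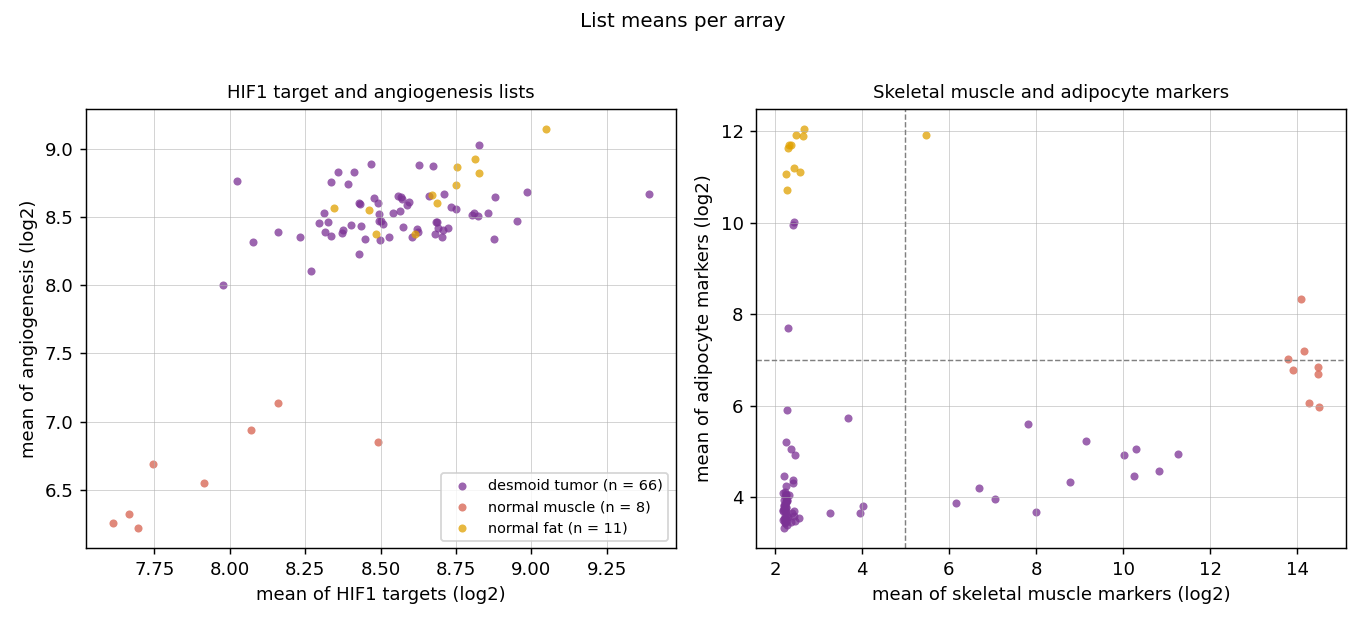
Per array, the mean log2 value of the HIF1 targets against that of the angiogenesis genes (left), and of the skeletal muscle markers against the adipocyte markers (right; dashed lines at 5 and 7). Muscle arrays average 6.62 on the angiogenesis genes, tumors 8.52 and fat 8.69, and 12 tumors lie over the muscle line and 3 over the fat line.

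Within the 66 desmoid tumors, the transcript levels of CTNNB1, PDGFRB and ABL1 did not track each other detectably. Links between their proteins or activities were not measured. CTNNB1 and PDGFRB had a Pearson r of -0.08 (permutation p 0.532, adjusted over 11 pairs 0.732) and a Spearman rho of -0.03 (p 0.788, adjusted 0.963). CTNNB1 and ABL1 had an r of -0.05 (p 0.679, adjusted 0.746) and a rho of -0.06 (p 0.605, adjusted 0.95), and PDGFRB and ABL1 an r of 0.18 (p 0.146, adjusted 0.267) and a rho of 0.17 (p 0.174, adjusted 0.419). Without the 2 arrays farthest from the median of the first gene, r was 0.10, -0.06 and 0.23. PDGFRB and its ligand PDGFD had an r of 0.25 (p 0.0396) that did not pass the correction (adjusted 0.218), with a rho of 0.26 (p 0.0345, adjusted 0.38) and an r of 0.21 without 2 arrays.

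HIF1A and VEGFA were the 1 pair past the threshold, and whether it passed depended on single arrays. Their r was 0.38 (permutation p 0.00297, adjusted 0.0327), with a rho of 0.20 (p 0.1, adjusted 0.419) and an r of 0.38 without the 2 arrays farthest in HIF1A. Desmoid 6 had the highest VEGFA of the tumors, 12.64 against 10.60 for the next, and without it r was 0.28 (adjusted p 0.144). Leaving out desmoid 4 gave an r of 0.29 (adjusted p 0.126), and leaving out desmoid 48, 52 or 58 an r of 0.36 (adjusted p 0.0749, 0.0664 and 0.063). Without desmoid 44, which shares a specimen number with another tumor array, r stayed at 0.38 (adjusted p 0.0367). Other alternatives gave a higher r: 0.50 (adjusted p 0.00132) given the muscle and fat markers, 0.48 (adjusted p 0.0107) without the tumors rich in those markers and 0.41 (adjusted p 0.0133) after quantile normalization. The other 6 pairs had r between -0.03 and 0.22 and none passed the correction: PDGFRB with ABL2 (0.22, adjusted p 0.258), PDGFA (-0.03, 0.824), PDGFB (0.19, 0.259) and PDGFC (0.06, 0.746), and CTNNB1 with HIF1A (0.21, 0.258) and VEGFA (0.09, 0.705).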

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

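The tests of the muscle transcripts and the counts over other splits of the arrays were chosen after the results were seen, and the set of values searched for a single array far from its group was narrowed, after a wider search, to the genes named in the text and the list means.

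In normal muscle, 12 of 76 values (54 genes and 22 list means), or 15.8%, had 1 array far from the other 7. Chance gives about 1 in 20, a rate that does not hold where arrays are tied at the lowest value, so the share does not show an excess. Normal muscle 5 stood apart in the mean of the lymphocyte and plasma cell markers, at 4.31 with the next array at 2.78, and in SDC1, at 2.53. Normal muscle 6 stood apart in the mean of the erythrocyte markers (5.96, next 4.68), in MFAP2 (3.43) and in EPB41L4B (6.06). Normal muscle 7 stood apart in COL11A1 (4.16), TMEM45A (7.27, next 3.82) and PPP1R1A (11.64). Normal muscle 8 stood apart in TF (6.82, next 2.44) and CIDEA (3.39), normal muscle 3 in LAMP5 (2.52) and normal muscle 1 in FBN2 (2.62). Of these genes, LAMP5 and FBN2 were at their lowest values in 7 of the 8 arrays, TF in 6, CIDEA and EPB41L4B in 5, MFAP2 in 3 and TMEM45A in 2. SDC1 lay near its lowest value in all 8, where small gaps stand out. No explanation was tested.

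EPAS1 and KDR were higher than muscle and lower than fat in the tumors. The 2 normal tissues themselves differed by -2.62 for EPAS1 (muscle minus fat, SE 0.24, limma adjusted p 7.46e-17) and by -3.05 for KDR (SE 0.31, adjusted p 6.40e-15). EPAS1 against muscle and KDR against fat were under 2-fold. What sets the 2 tissues apart was not tested.

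Of 100 splits of the arrays into groups of the same sizes, the real one included, 1 gave as many genes as the 4722 against muscle, the highest other giving 132. The same count of 1 held for the 2917 genes against fat (highest other 1229), the 4355 between muscle and fat (1041) and the 1704 called against both (0). No drawn split reached any of these 4 counts. These splits can give no share below 1 in 100, and with tissues this unlike the outcome could be foreseen. For the 13 gene list calls with the preset correlation, 59 splits gave as many. The other splits had a median of 13 and the highest gave 21. Chance was thus not excluded for the number of calls, and single lists were not judged. For the 2 list calls with an estimated correlation, both of fibroblast and matrix genes, only the real split gave as many. The highest other gave 1, with the same lowest share of 1 in 100.

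Skeletal muscle transcripts were present in 12 desmoid arrays, where the markers averaged 8.86 ± 1.71, against 14.21 ± 0.27 in normal muscle and 2.40 ± 0.40 in the other 54 tumors. Admixed resting muscle like that of the normal arrays was argued against by 3 of 7 genes tested, which relative to each array's muscle markers lay above every normal muscle array: MYH3 in 11 of the 12 tumors, MYH8 in 11 and ACTC1 in 12, against CHRNA1 in 2, MYOG in 2, MYOD1 in 3 and ANKRD1 in 0. On absolute levels, a test run first that excluded nothing, 0 genes did so in 5 or more tumors, and ACTC1 was also on in 39 of the other 54 tumors, so the argument rests on MYH3 and MYH8. Expression by the tumor cells themselves cannot be told apart: the share of tumors with a listed gene on was lower among the other 54 by a median ratio of 0.074, but those 54 were set apart by their low muscle markers, which fixes that outcome. Muscle in the tumor that differs from the normal arrays may be the source and stays open as well.

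Normal fat 9 and desmoid 44 had fewer values at the lowest level than other arrays of their groups, 25.01% and 26.39%, and each is 1 of 2 arrays whose labels share a specimen number, with partners at 29.85% (normal fat 11) and 31.07% (desmoid 36). A technical step shared by the 2 arrays was tested by correlating their deviations from their group means across genes, which are not independent replicates: r was 0.363, above all 725 other pairs of a fat and a desmoid array (highest 0.327). The shape of the value distribution alone cannot be told apart from other causes: after quantile normalization r was 0.284, still far above the 95th percentile of 0.102, but 1 other pair was as high (0.328). The values are consistent with a shared step in preparation or scanning, which the labels do not name. No biological explanation was tested.

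VEGFA was lower in desmoid tumors than in both normal tissues, and stayed called in both comparisons under all 32 alternatives of the limma fit. An immediate-early response of the tissue before freezing was argued against as the whole cause, since with the mean of those genes as a covariate the differences were -1.95 (SE 0.25) against muscle and -2.00 (SE 0.26) against fat. Adipocytes and muscle fibres as the source of VEGFA could not be decided. With both marker means as covariates the differences were -2.78 (SE 0.40) and -1.65 (SE 0.48, limma adjusted p 0.00811). Marker levels hardly overlap between tissues, so that fit extends beyond what each group shows, and no conclusion is drawn from it. A lower VEGFA output of the tumors themselves and a source in adipocytes and muscle fibres both stay open as hypotheses. Handling before freezing, which the labels do not detail, was tested through the immediate-early genes alone.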

How the results depend on the processing

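Leaving out normal fat 9 and desmoid 44, desmoid arrays rich in muscle or fat transcripts, or desmoid 6, and both scalings of the gene lists, were chosen after seeing the data.

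All 128 values of the 4 gene counts over 32 alternatives stayed within 1.5 times the reported count. Apart from single arrays left out, they ranged from 4001 to 5049 against muscle, 2376 to 3133 against fat, 3694 to 4678 between muscle and fat and 1438 to 1846 against both. Without each normal array in turn they ranged from 4685 to 4750, 2899 to 2977, 4295 to 4397 and 1685 to 1743. Keeping arrays of 1 specimen number apart changed nothing by construction, since none had been averaged, and the robust fit without the trend changed no call, so neither tested these counts. All 7 clustering alternatives stayed past the permutation threshold, with a Rand index from 0.616 (complete linkage) to 0.912 (HIF1 targets alone).

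The number of gene list calls, 13, was 2 with an estimated correlation and 31 with fry, which asks another question, and 12 to 16 in the other 6 alternatives. Angiogenesis against muscle missed the threshold with an estimated correlation (adjusted p 0.0703), and HIF1 targets against muscle passed it with fry (9.29e-06). The estimated correlation ends calls by construction where genes of a list move together between arrays. Of 354 list tests under alternatives, 313 kept their side of the threshold, 27 passed it newly and 14 lost it. Wnt targets against muscle were lost among genes with a group mean of at least 4 (0.0926), and adipocyte markers against muscle with probe sets averaged (0.051) and with median centring (0.337); the cause was not tested.

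The 1 correlation past the threshold, HIF1A with VEGFA, fell to an r of 0.28 without desmoid 6, which left 0 of 11 pairs called; leaving out any of 4 other tumors singly also ended the call, and the cause was not tested. In 65 of 66 values of the 11 pairs the side of the threshold was kept. Of 3450 values of named genes, 3426 kept their side, 10 newly passed and 14 fell under it. These belonged to PDGFRB, CTNNB1 and FLT1 against fat and ABL1, PDGFRA, FLT1 and MARCO against muscle. MARCO, at -0.95, was called in 8 alternatives (-1.43 to -1.01), 5 of them without 1 normal muscle array (1, 2, 3, 6 or 8). Uncalled values that changed sign were counted as kept, and no called value reversed.

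Alternatives that need control probe sets (RNA quality as a covariate, a partial correlation and a comparison of probe positions) were not run, since the table holds none. No paired analysis was possible because the labels give no shared replicate numbers between tissues. Background limits the smallest levels: about 30% of values lay at the lowest level, where differences are compressed.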

Other observations

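The test of positional genes was chosen after the result was seen, and the glucocorticoid list was written after ZBTB16 and PDK4 had been seen to be lower, without those genes.

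Desmoid tumors may carry a lower glucocorticoid response than both normal tissues, a hypothesis raised by ZBTB16 and PDK4, which glucocorticoids induce. Of 15 measured genes that glucocorticoids induce, 10 were called lower against both tissues, where 10000 random lists matched on mean expression had a median of 1 and a 95th percentile of 3, and 0 reached 10. FKBP5 differed by -6.20 from muscle and -2.11 from fat, TXNIP by -3.30 and -3.17 and BCL6 by -2.88 and -2.29. CRISPLD2 went the other way, at 4.39 and 2.58, as did CCND3 against muscle, at 1.51 (adjusted p 1.64e-09), though not against fat, at -0.40. The random lists were not matched on expression in both muscle and fat, so genes that these tissues share for other reasons remain open, as does any difference in treatment or surgery.

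Positional identity genes, which mark where in the body a fibroblast comes from, varied more between tumors than random lists matched on the mean of the 3 tissues. The level in tumors, on which the SD can depend, was not matched. SHOX2, for example, averaged 10.58 in tumors, 3.26 in muscle and 4.62 in fat. The median SD of the 21 measured genes over the 66 desmoid arrays was 0.70, where matched random lists had a median of 0.39 and a 95th percentile of 0.52, and 14 of 10000 reached it. ZIC1 had an SD of 1.82, HOXC10 of 1.68 and HOXB7 of 1.53. Differences in body site between tumors are a candidate explanation, which could not be tested because no site was used here.

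Of the 66 desmoid arrays, 3 had a mean of the adipocyte markers over 7, against a group mean of 4.28 ± 1.27, and the highest reached 10.03, where fat arrays ranged from 10.72 to 12.06. Without these and the 12 arrays rich in muscle markers, 51 tumors gave 4768 genes against muscle and 3038 against fat.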
